A study of Mus musculus with 8 samples.

How the data were processed

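Gene expression was measured with Illumina MouseRef-8 v2.0 bead arrays in V6.5 mouse cells. V6.5 is a mouse embryonic stem cell line. Per the labels, the cells were turned into epiblast-like cells by withdrawal of LIF and the 2i inhibitors for 3 days, and total RNA was taken with Trizol. The labels gave 4 GRHL2 wildtype subclones and 4 GRHL2 knockout clones, 1 array each, and the groups were taken from the genotype label. The number of passages, the day of culture and the array chip of each sample were not given in the sources used here, so no slide or day could be set as a block. P-values therefore set the difference of the groups against the spread between arrays within a group. With 1 array each, clone, culture and hybridization cannot be told apart in that spread.

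Per the file headers, the deposited probe profile held for each of 25697 probes the mean bead intensity, its standard error, the number of beads and a detection p-value on each array. From the values, these intensities were neither background-subtracted nor normalized. The authors also deposited a table of log2 values after quantile normalization of the 8 arrays. It was equal to log2 intensity quantile normalized with no background step, with a largest difference of 4.97e-14 between sorted values, and the deposited series value table was identical to it. Its columns had a median of 7.20. The submitters' processing notes name limma. The authors' deposited comparison table gave log2 fold changes of knockout minus wildtype, p-values, adjusted p-values and moderated scores (t and log odds). Its fold changes differed by at most 0.0142 from those of an array-weighted limma fit, and by up to 0.46 from those of an unweighted fit. Array weighting by the authors is not stated in the sources used here.

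Intensities were background-corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16. Probes with a detection p under 0.05 on at least 4 arrays were kept, which left 12790 probes. Gene symbols came from the platform annotation of the probes: 23978 probes had 1 symbol, 0 had several and 1719 had none here. Of all probes, 23962 had an Entrez gene identifier in the RefSeq gene table of assembly GRCm38.p6, through which 0 symbols changed. Where a gene had several retained probes, that with the highest mean log2 value stood for the gene, which left 8830 genes, 2294 of them with more than 1 retained probe. Probes without a symbol entered normalization and no gene test. Chromosomes of genes were taken from the same gene table.

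Knockout was compared with wildtype by lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over the 8830 genes and a threshold of 0.05. Values are log2 normalized intensities, fold changes are knockout minus wildtype on that scale, and SE is the moderated standard error. Where a gene was detected on none of the arrays of a group, the change was given as at least the distance to the lowest intensity of any detected probe of those arrays. Single values (array brightness, list means, principal component scores) were compared by exact two-sided permutation over the 70 assignments of 4 arrays each, whose smallest possible p is 0.0286. For 24 gene lists written before the data were examined, camera of limma was run on the 22 lists with at least 4 measured members, with an inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the lists. Alternatives were camera with estimated correlations, camera on ranks and fry.

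The genes named in the text were chosen by a rule written before the data were examined: Grhl2; the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap; and in each list up to 4 members with the largest changes among those past the threshold, or up to 2 of its brightest members as values where none was. Other genes are named only where the text says so, or as further members of a list.

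The fit was tested on simulated data drawn from the 8830 genes. With 100 genes changed at each size, it recovered 78% of the simulated log2 changes of 1 and 13% of those of 0.5. Of its calls 4.21% were false. Far fewer genes changed there than were called in the data, so the adjusted threshold was stricter and these shares do not carry over. Camera recovered 5 of 5 simulated shifted lists and called 0 of 15 others. The simulated genes varied independently, so this does not cover lists whose members vary together. Alternatives covered background correction, between-array normalization, the authors' tables, the detection filter, the choice of probe, variance moderation, array weights, the threshold, the clone number as a block, and each array left out in turn. No per-sample column of the files was left unmapped. A slide block was not run. No 2 arrays held identical signals.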

Results

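The arrays compared epiblast-like cells with and without GRHL2, a grainyhead-like transcription factor of epithelia, after the cells had left the naive pluripotent state. There were 4 wildtype subclones and 4 knockout clones. The title of the series puts the question as how GRHL2 acts on the transcriptional network of pluripotent cells at this stage. Between 12414 and 13250 of the 25697 probes were detected on each array. The arrays of the groups differed in brightness: mean intensity before normalization was 703 ± 32.4 (SD, n = 4) in wildtype and 508 ± 51.5 (SD, n = 4) in knockout, 72.3% of wildtype (exact permutation p = 0.0286, the smallest possible). Correlations of normalized values were 0.977 to 0.994 between arrays of a group and 0.965 to 0.984 between groups. The median within-group SD per gene was 0.19 in both groups on the log2 scale. The number of arrays limits the precision.

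Grhl2 itself was lower in knockout, by 1.13 on the log2 scale (SE 0.30, limma adjusted p = 0.0369), from 8.84 ± 0.60 to 7.71 ± 0.43 (SD, n = 4 each). The knockout arrays held 45.6% of the wildtype level and all 4 lay below all 4 wildtype arrays (exact permutation p = 0.0286). The probe was detected on every knockout array, with intensities of 219 to 326 against 457 to 1123 in wildtype. Its position relative to the deleted part is not given in the sources used here, so a remaining signal does not speak against the labels. The call was near the threshold: without wildtype replicate 1, 2 or 4 or knockout replicate 2, 3 or 4, the adjusted p rose above 0.05. It rose up to 0.0835, while the log2 change stayed between -1.36 and -0.88. Grhl1, a related factor, fell by 0.93 (SE 0.09, adjusted p = 0.00121).

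In knockout, Cldn4, Ap1m2, Rab25 and Krt8, which are genes of epithelial cells, were lower, and Gbx2, Vim and the homeobox genes Hoxb5 and Hoxb2 were higher. Of 8830 genes tested, 1211 changed (limma, adjusted p under 0.05), 578 higher and 633 lower in knockout. The near-even split holds for quantile normalization of arrays that differed in brightness: it was 36 higher and 5735 lower without normalization between arrays, and 236 and 1867 with median scaling. Changes of at least 2-fold were found for 137 genes, 46 higher and 91 lower, against 30 with no background correction or on the authors' deposited values and 55 with normexp at an offset of 50. The groups did not overlap for 2047 genes (23.2%, against 2.86% by chance), and 2826 genes had an unadjusted p under 0.05. The first principal component held 41.8% of the variance and separated the groups (exact permutation p = 0.0286). The count moved with single arrays: it was 610, 559 and 510 without wildtype replicates 1, 2 and 4, and 609, 566 and 657 without knockout replicates 2, 3 and 4. Wildtype replicate 3 and knockout replicate 1 stood apart on the third and second components. When both were left out 1743 genes passed, 1011 of them among the 1211. With array brightness entered into the fit, a choice made after the data were seen, 16 genes passed the threshold, 12 of them among the 1211. The median absolute log2 change of the 1211 genes then went from 0.63 to 0.55 and 93.6% of them kept their sign, while the median SE rose from 0.14 to 0.35.

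Claudin 4 (Cldn4), a tight junction protein, had the largest measured fall, from 11.03 ± 0.60 to 8.14 ± 0.14 (SD, n = 4 each), which was 7.41-fold (adjusted p = 0.000572). Of the changed genes, 29 were detected on no knockout array, and only a lower bound can be given for their falls. Ap1m2, the epithelial subunit of the AP-1 clathrin adaptor, was 6.78-fold lower and Tfap2c, a factor of trophoblast and germ cells, 6.15-fold lower. Rbm47, an RNA-binding protein, fell 6.08-fold and was detected on 1 of 4 knockout arrays. The iron exporter Slc40a1 (ferroportin) was 5.50-fold lower. Rab25, a small GTPase of apical recycling, was detected on no knockout array and was at least 4.19-fold lower (adjusted p = 1.51e-05). The keratin gene Krt8 fell 4.61-fold, the cathepsin gene Ctsc 4.16-fold, Tmem54 4.09-fold, and both the membrane protease gene Prss8 and Prom2 4.00-fold, Prom2 being detected on 1 knockout array. Zfp987 was 4.61-fold lower and was detected on 2 knockout arrays. Wildtype replicate 3 lay above the others for Cldn4 (11.93), Krt8 (12.49) and Tfap2c (10.86). Without that array the log2 change of Tfap2c went from -2.62 to -1.87. Tfap2c lost its call without wildtype replicate 4 or knockout replicate 2 or 3, with adjusted p up to 0.0560, and both its other probes were lower without passing (-1.90, adjusted p = 0.0608, and -1.28, adjusted p = 0.166). Zfp987 lost its call without any of 5 arrays (wildtype replicates 2 and 4, knockout replicates 2, 3 and 4), up to 0.0872, and its log2 change went from -2.20 to -1.57 without wildtype replicate 1. The calls of Tfap2c and Zfp987 were also lost with no background correction. A second Prom2 probe differed in sign and was not past the threshold (0.26, adjusted p = 0.266).

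Gbx2, a homeobox factor, had the largest measured rise, from 8.73 ± 0.55 to 11.82 ± 0.56 (SD, n = 4 each), 8.46-fold (adjusted p = 0.00121). The kinesin gene Kifc2 rose 5.33-fold and was detected on 2 of 4 wildtype arrays, and Ulk4 rose 3.77-fold and was detected on 1. Dipk1a rose 3.94-fold. Vim, the intermediate filament protein of mesenchymal cells, rose 3.81-fold, from 8.53 ± 0.43 to 10.46 ± 0.34 (adjusted p = 0.00230). The homeobox genes Hoxb5 and Hoxb2 rose 3.72-fold and 2.71-fold, Upp1 (uridine phosphorylase) 3.25-fold, Fez1 3.19-fold, the helix-loop-helix factor Tcf15 2.73-fold, Dpysl4 2.65-fold and the receptor gene Tnfrsf19 2.62-fold. Hoxb5 passed the threshold with all arrays (adjusted p = 0.0207) and lost it without wildtype replicate 2 or 4, up to 0.0544.

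**Figure D1:**
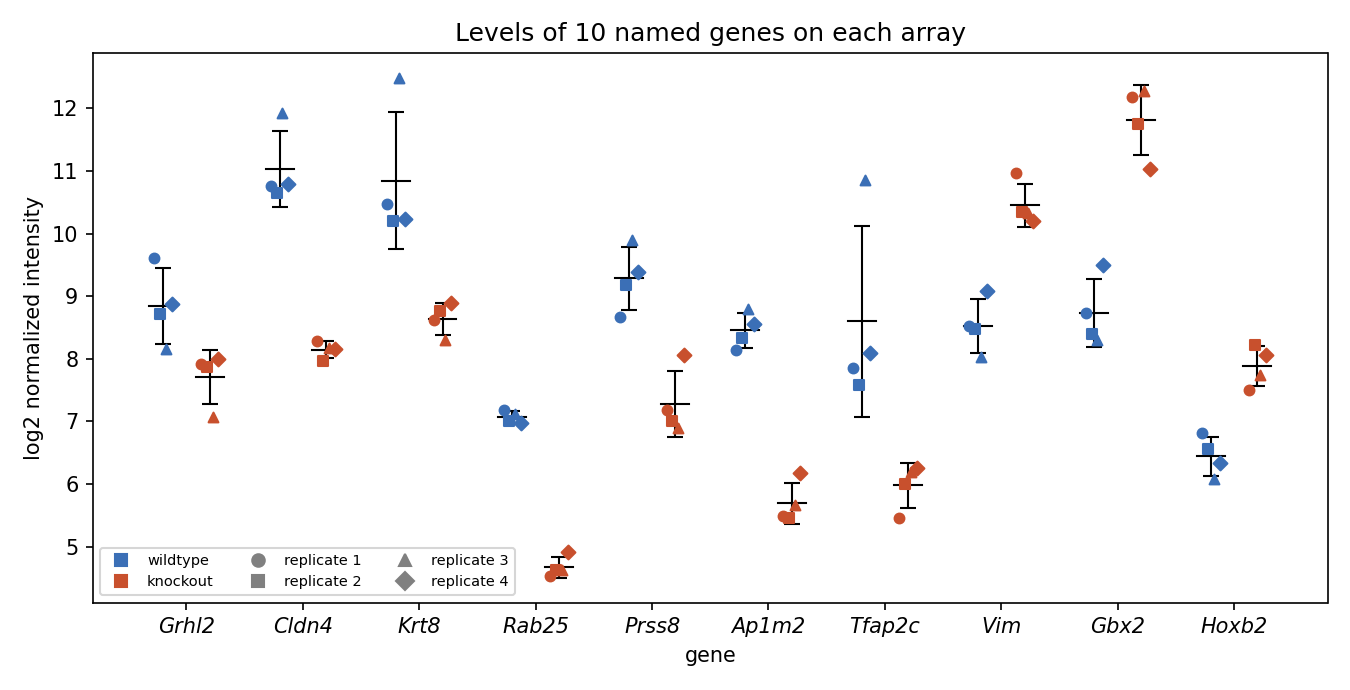
Log2 normalized intensity of 10 named genes on each array, 4 wildtype and 4 knockout, with marker shapes for replicate numbers, and lines with bars for the mean and SD of each group. Wildtype replicate 3 stands above the other wildtype arrays for Krt8 (12.49) and Tfap2c (10.86). The groups do not overlap for any of the genes drawn, which the rule of choice required of all but Grhl2.

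In 3 lists of epithelial genes, 26 of 60 measured members fell and 1 rose. At an estimated correlation none of these lists passed camera (adjusted p = 0.183, 0.106 and 0.504 for the lists in the order that follows). In the list of epithelial regulators and membrane proteases, 13 of 23 measured members fell and 0 rose (adjusted over the list alone, 13 fell), with a mean log2 change of -0.88. Besides Ap1m2, Rab25, Prss8 and Prom2, the epithelial factor Elf3 fell by 1.70, the splicing regulators Esrp1 and Esrp2 fell by 0.88 and 1.11 (Esrp2 was detected on 2 knockout arrays), and Cdh1 (E-cadherin) fell by 0.92. In the list of adherens junction, desmosome and keratin genes, 8 of 15 fell and 0 rose (9 fell adjusted over the list alone), with a mean of -0.79. Among these, Lad1 was detected on no knockout array and was at least 3.15-fold lower, Ppl (periplakin) fell by 1.17, and Krt18 fell by 1.60 with a call that was lost when any array other than wildtype replicate 3 was left out (adjusted p up to 0.105) or with no background correction; without wildtype replicate 3 its log2 change was -1.04. In the list of tight junction and apical polarity genes, 6 of 24 fell and 1, Ildr1, rose by 0.65 (the same numbers adjusted over the list alone), with a mean of -0.41. The call of Ildr1 was lost with no background correction. Marveld3 fell by 1.67, Cldn6 fell by 1.62 and F11r fell by 1.08.

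These lists and that of trophoblast genes were past the threshold with camera at its preset correlation, 4 of 22 lists (adjusted p = 2.76e-10, 1.20e-07 and 0.0302 for the epithelial lists in the order given, and 0.000989 for trophoblast). With an estimated correlation 0 of 22 lists passed, the adjusted p being 0.607 for trophoblast. The unadjusted p was then under 0.05 for 3 lists, those of regulators (0.0166), of adherens junction, desmosome and keratin genes (0.00483) and of stress genes (0.0420). Of the 35 splits of the arrays, 15, the real one among them, gave at least 4 lists at the preset correlation. A split of wildtype replicate 1 and knockout replicates 1, 2 and 3 against the rest gave 3.09e-12 for the regulators. That split still parts most arrays by genotype, so it holds a part of the genotype difference. The mean of each of these 4 lists was lower on all knockout arrays than on all wildtype arrays (exact permutation p = 0.0286 each, 0.0857 after adjustment over the 24 lists). With the same p, the means of the Nodal and activin, hypoxia and glycolysis, and grainyhead family lists were lower on all knockout arrays, by -0.23, -0.16 and -0.44, and that of the stress list was higher, by 0.20. The tight junction list lost its call without wildtype replicate 3 (adjusted p = 0.0749) or knockout replicate 2 (0.0682), and with camera on ranks (0.101). With fry, which asks whether a list moves one way on balance, 5 lists passed, the 3 epithelial lists (adjusted p = 0.000694, 0.000694 and 0.0116 for regulators, adherens junctions and tight junctions), the stress list (0.00276) and the core pluripotency list (0.0294). The trophoblast list did not (0.170).

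**Figure D2:**
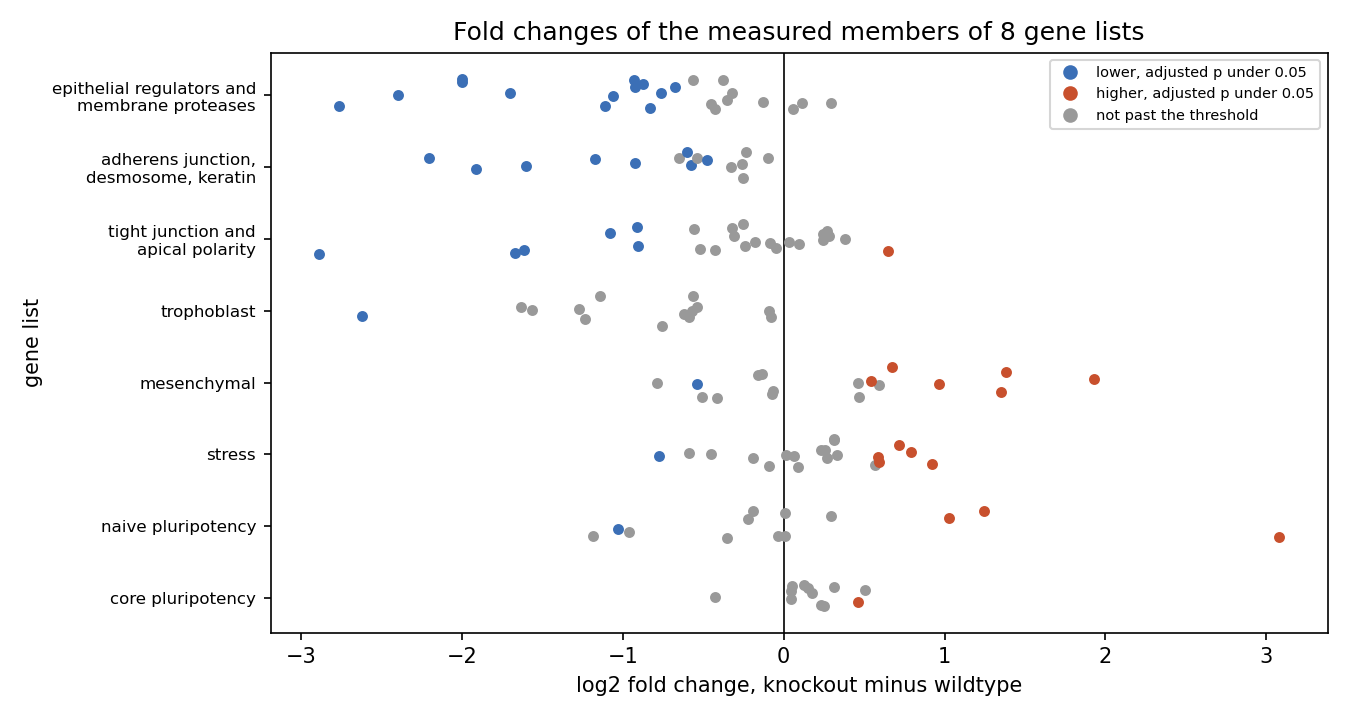
Log2 fold change (knockout minus wildtype) of each measured member of 8 gene lists, 1 point per gene, coloured by direction where the limma adjusted p was under 0.05 and grey otherwise; vertical position within a list is arbitrary. In the regulators list 13 of 23 genes fell, while the trophoblast list held 1 called gene of 14.

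The trophoblast list held 14 measured genes, of which Tfap2c alone was past the threshold (6 fell adjusted over the list alone), with a mean log2 change of -0.95. Its mean on wildtype replicate 3 was 7.73, against 6.06 to 6.24 on the other wildtype arrays and 5.35 to 5.83 on the knockout arrays. Without that array the mean change was -0.56.

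Among mesenchymal genes, 6 of 17 rose and 1 fell (8 and 1 adjusted over the list alone). Vim, the zinc finger repressor Zeb1 (1.38), Tgfbi (1.35, detected on 3 wildtype arrays) and Twist2 (0.97) rose, as did Axl and Mmp14, while Tcf4 fell by 0.54. The list was not past the threshold (camera adjusted p = 0.107). Without wildtype replicate 4 and without knockout replicate 4 it passed, at 0.0418 and 0.0347, as it did with the mean of all probes of a gene (0.0457) and with no detection filter (0.0274). With an estimated correlation its adjusted p = 0.610. Tgfbi lost its call without wildtype replicates 1, 2 or 3 or knockout replicate 3, and Mmp14 with any array other than wildtype replicate 4 left out.

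Pluripotency genes moved in both directions. Of 13 naive pluripotency genes, Gbx2, Socs3 (1.24) and Klf2 (1.03) rose and Nanog fell by 1.03 (SE 0.11, adjusted p = 0.00158; 3 rose and 1 fell adjusted over the list alone). The median of the list was -0.03 and its mean 0.13 (camera adjusted p = 0.999). Klf2 lost its call without wildtype replicates 2 or 4 or knockout replicates 3 or 4. Of 11 genes of the formative and primed states, Pim2 (0.94) and Pou3f1 (0.88) rose (adjusted over the list alone, 2 rose and 1 fell), and of 12 core pluripotency genes Utf1 rose by 0.46 (2 rose adjusted over the list alone), a call lost without wildtype replicate 2 or 4. Neither list was past the threshold with camera (0.839 and 0.185); the core list passed with fry (0.0294), and its camera adjusted p = 0.607 with an estimated correlation.

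Signalling and lineage lists were not past the threshold with camera either. Of 15 FGF and ERK response genes, Etv1 (1.20) and Il17rd (0.64) rose, while Phlda1, Egr1 and Junb fell by 1.33, 1.11 and 0.66 (camera adjusted p = 0.963; median 0.05, mean -0.04; adjusted over the list alone, 2 rose and 3 fell). Id3 fell by 0.92 among 12 Nodal and activin response genes (0.185), Sfrp1 rose by 0.92 among 11 Wnt response genes (0.869), and Fzd6 fell by 0.77 among 12 planar polarity genes (0.663). Adjusted over the list alone, 2 Nodal genes fell, 1 Wnt gene rose and 1 fell, and 1 polarity gene fell. Among germ layer lists, Irx3 rose by 1.29 in 8 neuroectoderm genes (0.185) and Hoxb1 by 1.15 in 10 primitive streak and mesoderm genes (0.782). Of 13 endoderm genes Lama1 rose by 0.91 (detected on 3 wildtype arrays) and Col4a1 fell by 0.79 (0.950). Adjusted over the list alone, 1 neuroectoderm gene rose, 1 streak gene rose and 3 fell, and 2 endoderm genes rose and 1 fell. Stk31, detected on 1 knockout array, fell by 0.91 among 12 germline and 2-cell-like genes (0.375), Ccn1 fell by 0.64 among 11 feeder fibroblast genes (0.663), and Ndn rose by 0.37 among 17 imprinted genes (0.782; adjusted over the list alone, 1 germline gene fell and 0 fibroblast or imprinted genes changed). The calls of Lama1, Col4a1, Ccn1, Junb, Il17rd, Fzd6 and Ndn were each lost when at least 1 array was left out, and that of Ndn with every array.

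Of 20 stress genes, 5 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0802, and 0.0410 on the authors' deposited normalized values; fry adjusted p = 0.00276, and camera adjusted p = 0.308 with an estimated correlation). This list joined genes of amino acid stress and of heat shock. Chac1 (0.92), Sesn2 (0.79), Shmt2 (0.72), Trib3 (0.59) and Phgdh (0.59) rose. The heat shock gene Hspa1a fell by 0.77 and was detected on 1 knockout array. Of 17 p53 response genes, Sesn2 and Gtse1 (0.55) rose and Trp53inp1, Phlda3 and Ccng1 fell by 0.57, 0.53 and 0.48 (camera adjusted p = 0.869; adjusted over the list alone, 3 rose and 4 fell). Of 22 cell cycle genes, Pcna, Mcm6, Cdk1 and Cdc6 fell by 0.96, 0.79, 0.53 and 0.43 and 0 rose, while 4 rose and 5 fell adjusted over the list alone (0.950; median 0.04, mean -0.06). Each of these p53 and cell cycle calls other than Sesn2 was lost when at least 1 array was left out, as were those of Trib3, Phgdh and Hspa1a. Another Mcm6 probe differed in sign (0.098, adjusted p = 0.698), and other probes of Sesn2 (0.43, adjusted p = 0.259), Gtse1 (0.19, 0.463), Trp53inp1, Phlda3 and Cdc6 had the same sign without passing. Of 13 hypoxia and glycolysis genes 0 passed (camera adjusted p = 0.449), and adjusted over the list alone 1 rose and 3 fell. The brightest, Ldha, was 14.12 ± 0.22 in wildtype and 14.00 ± 0.09 in knockout, and Slc2a3 was 13.27 ± 0.36 and 12.82 ± 0.28 (SD, n = 4 each).

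The authors' deposited table held 2214 probes with an adjusted p under 0.05, 1114 higher and 1100 lower in knockout. Among the probes that stood for the 8830 genes it called 1603, of which 1079 were also called here, all with the same sign. Independent lists would share 110 genes with the same sign. Across genes, which are not independent replicates, the fold changes correlated with r = 0.919. Both rest on the same arrays. Among genes called in both, the fold changes here were a median of 1.41 times those of the authors' deposited table, whose values from the arrays show no background correction.

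Gene groups were also read by chromosome, since 2 arrays stood apart. On wildtype replicate 3 the genes of chromosome 6 were higher than on the other wildtype arrays, by a median of 0.40, and 88.3% of them shifted that way. On knockout replicate 1 the genes of chromosome 8 were lower than on the other knockout arrays, by a median of -0.43, and 90.7% of them shifted that way. Other medians of a chromosome on an array lay between -0.16 (chromosome 6 on knockout replicate 1) and 0.15. For the other arrays of these groups the reference included the shifted array, which moved their medians of that chromosome the other way. Of the 1211 changed genes, 61 lay on chromosome 6 (51 lower in knockout) and 55 on chromosome 8 (39 lower).

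**Figure D3:**
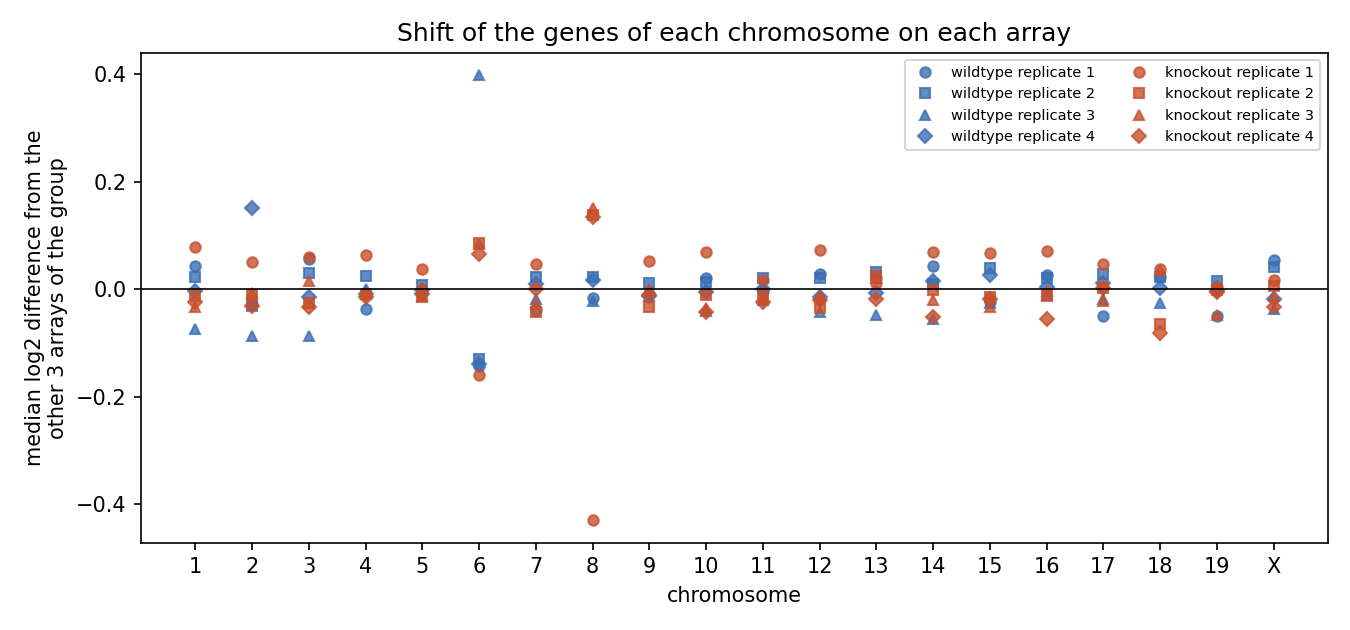
Median log2 difference of the genes of each chromosome on each array from the mean of the other 3 arrays of its group, 1 point per array, coloured by group. Chromosome 6 on wildtype replicate 3 (0.40) and chromosome 8 on knockout replicate 1 (-0.43) lie apart from all other points.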

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

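The tests of normalization on chromosomes and of wildtype replicate 3 for the trophoblast list were chosen after the results were seen. Of 280 groups of 4 arrays tested for a value far from the others, 20 stood out, where chance gives about 1 in 20, or 14.

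The 1211 changed genes and the fall of the epithelial genes went with a difference in array brightness, which shared 85.2% of its variance with the genotype. With brightness in the fit, changed genes kept a median of 0.933 of their fold change (0.891 to 0.977 with arrays left out in turn). The epithelial genes kept 1.34 times theirs (1.19 to 1.80). These ratios cannot tell brightness from genotype, since little of the brightness varied apart from genotype. The changed genes had also been chosen for a gap between the groups. Brightness as a cause is therefore left open. Only 16 genes passed with brightness in the fit, since the median SE rose from 0.14 to 0.35. The median absolute log2 change went from 0.63 to 0.55. With the trophoblast score in the fit the epithelial fall kept 0.724 of its size (0.679 to 0.906). The trophoblast list was itself lower on the knockout arrays, and within wildtype it stood apart on replicate 3. The fit therefore cannot decide whether a differing share of trophoblast-like cells was a cause. The real split gave more changed genes, rises, falls and 2-fold changes than any of the other 34 splits. Those gave 0 genes (limma), and at most 1481 at an unadjusted p under 0.05, against 2826. With 4 arrays each, 1 of 35 is the smallest share possible, so this argues against chance without excluding it. These counts come from 1 fit and are not separate results. The other splits mix the genotypes, which widens the spread within their groups. At least 4 lists passed in 15 of 35 splits, the real one included, with up to 8, so chance was not excluded for the lists.

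Genes of chromosome 6 were higher on wildtype replicate 3 than on the other wildtype arrays, by a median of 0.40 over 428 genes, and genes of chromosome 8 were lower on knockout replicate 1, by -0.43 over 492 genes. None of 10000 random lists matched on expression came as far, with extremes of 0.059 and -0.034, and other normalizations gave 0.23 to 0.39 and -0.47 to -0.29, which argues against uneven normalization. Each chromosome's genes, parted by gene order (assembly GRCm38.p6) into 3 sets of like size, shifted alike, the smallest shift being 0.33 on chromosome 6 and -0.41 on chromosome 8, so a candidate explanation is a copy number of the whole chromosome that differed in these cultures. Set against the knockout arrays, chromosome 6 was at 0.50 on wildtype replicate 3 and at 0.092 on the other wildtype arrays; set against the wildtype arrays, chromosome 8 was at -0.37 on knockout replicate 1 and at 0.053 on the other knockout arrays. Copy numbers were not measured, and 1154 genes changed when both chromosomes were left out.

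The trophoblast list was far higher on wildtype replicate 3 (mean log2 7.73, the others 6.06 to 6.24), as were Tfap2c (10.86), Krt8 (12.49), Krt18 (11.27), Cldn4 (11.93), Elf3 (8.34), Map7 (7.52) and the mean of the adherens junction, desmosome and keratin list (9.40). Without that array the fall shrank from -0.95 to -0.56, still more than the SD of the other wildtype arrays (0.10) and of the knockout arrays (0.21), which argues against that array alone as the cause. No test separated trophoblast-like cells in that culture from a shift within all its cells.

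Further values far from the others of their group were as follows. On knockout replicate 3, Grhl2 was 7.06 (the others 7.86 to 7.99), Upp1 was 13.23 (12.41 to 12.55), Eif2s3y was 8.11 (4.64 to 4.77) and the median number of beads was 37 (35 on the others). On knockout replicate 1, the germline and 2-cell-like list had a mean of 6.67 (7.91 to 8.08) and the feeder fibroblast list 8.19 (7.74 to 7.79). Centred on the mean of all 8 arrays, the chromosome medians that stood out were 0.40 for chromosome 6 on wildtype replicate 3, -0.24 for chromosome 6 and -0.35 for chromosome 8 on knockout replicate 1, and -0.055 for chromosome 19 on wildtype replicate 1. Ocln was 6.82 on wildtype replicate 1 (6.32 to 6.39). Knockout replicate 2 had 12719 detected probes (12414 to 12442). Of 753 retained probes with no gene symbol here, which entered no comparison, 88 passed the test over all retained probes.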

How the results depend on the processing

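Leaving out both arrays that stood apart, leaving out chromosomes 6 and 8, and entering array brightness were chosen after the data were seen. A set of 89 genes past the threshold was followed: those named by the rule, all other called list members and the called Hox genes. Of these, 57 stayed past it with each array left out in turn, and 0 changed sign. With no background correction or on the authors' normalized table, 8 lost their calls, among them Tfap2c, Krt18, Zfp987, Ildr1, Hoxb4, Hspa1a and Lama1, with no detection filter 13 besides Grhl2, with normexp 2 and with the replicate block 18. With array brightness 16 genes changed, 6 higher and 10 lower, 16 of them at least 2-fold. Without normalization between arrays 5771 genes changed (36 higher, 5735 lower, 1236 at least 2-fold), and with median scaling 2103 (236 higher, 1867 lower, 291 at least 2-fold). Their share of higher genes was 0.624% and 11.2%, against 47.7%, since these scalings moved the median of all genes by -0.58 and -0.19. Of the 89 genes, 7 changed direction without normalization between arrays (Utf1, Gtse1, Ndn, Mmp14, Il17rd, Phgdh and Hoxa13) and 0 with median scaling. Relative to the median of all genes, which is itself a scaling, 0 did. Array weights gave 2175 genes (1056 higher, 1119 lower). An adjusted p under 0.01 left 167 (67 higher, 100 lower, 75 at least 2-fold). Without both arrays that stood apart, 958 genes were lower. Leaving out each array gave 510 to 1440 changed, 241 to 647 higher, 269 to 793 lower and 117 to 162 at least 2-fold. No background correction, the authors' normalized table and the series value table gave 30 genes changed at least 2-fold, and normexp with offset 50 gave 55; added background shrinks fold changes. The replicate numbers did not pair the arrays: same-number correlations were -0.077 to 0.046, and 1 of 4 wildtype arrays correlated best with its own number. With the number as a block 671 genes changed (287 higher, 384 lower), with fewer residual degrees of freedom.

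Grhl2 kept its log2 change of -1.13 with no detection filter but not its call (adjusted p = 0.0675, more genes tested), and ranged from -1.36 to -0.88 with arrays left out, the adjusted p from 0.0170 to 0.0835. Lists past the threshold numbered 0 with an estimated correlation, 7 with no detection filter (of 24 tested, 6 of them among the 22) and 3 to 5 with arrays left out; the cause was not tested. At the authors' adjusted p under 0.01 the overlap was 464. Other probes were compared singly only for the genes named by the rule. Of these, probes differed in sign for Prom2 (0.26), Mcm6 (0.098) and Ccn1 (6.92e-05). A further 12 probes had the same sign without passing (of Tfap2c, Sesn2, Hoxb1, Gtse1, Phlda3, Trp53inp1, Cdc6, Pim2, Ccn1 and Mcm6). Over all changed genes, 353 of 426 other retained probes (82.9%) had the same sign, and 1 of opposite sign passed the threshold. Signal near background limits the folds of Rab25 and Lad1, and of genes detected on 1 to 3 arrays of a group (Rbm47, Prom2, Zfp987, Esrp2, Stk31, Hspa1a, Ulk4, Kifc2, Tgfbi, Lama1, Hoxb1 and Hoxb4). A slide block was not run, as no chip is given.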

Other observations

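The tests of Hox genes were chosen after several were seen among the largest rises. Of 15 measured Hox genes, the homeobox genes of the body axis, 5 rose and 0 fell in knockout: Hoxb5 (1.90, SE 0.42), Hoxb2 (1.44, SE 0.19), Hoxb1 (1.15, SE 0.22; detected on 3 wildtype arrays, and another probe at 0.61, adjusted p = 0.173), Hoxb4 (0.99, SE 0.29; detected on 2) and Hoxa13 (0.58, SE 0.15). The calls of Hoxb5, Hoxb4 and Hoxa13 were lost when at least 1 of several arrays was left out, with adjusted p up to 0.0544, 0.115 and 0.0881. Relative to the median of all genes, 14 of 15 were above 0 under each of the normalizations compared. The 10 that did not pass, 9 of them above 0 and Hoxd8 at -0.60 (SE 0.20, limma adjusted p = 0.0762), had a mean change of 0.42 (exact permutation p = 0.0571). Of these 10, Hoxb7 had a wildtype mean of 6.24, and the others lay between 4.86 (Hoxd11) and 5.41 (Hoxa7). Rab25, detected on no knockout array, had a mean of 4.67 there, so signal near background limits most of these changes. Whether the rise may be shared by the Hox genes or lies with a few of them is left open.

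Eif2s3y, a gene of the Y chromosome, was detected on all 4 wildtype arrays and on 1 knockout array, and its groups overlapped (log2 change -1.90, SE 0.89, limma adjusted p = 0.171). It was 7.96, 9.18, 6.99 and 5.65 on wildtype replicates 1 to 4, and 4.66, 4.77, 8.11 and 4.64 on knockout replicates 1 to 4. Uty, the other measured gene of the Y-linked list, was 5.25 ± 0.41 in wildtype and 5.05 ± 0.40 in knockout (SD, n = 4 each).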
